A study of Mus musculus and Homo sapiens with 16 samples.

How the data were processed

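The series holds 16 samples: 8 ChIP libraries with a peak list each and 8 inputs, whose own files were not used here. Peaks were called by the authors with HOMER findPeaks in each ChIP library against its own input, per the file headers, with no pooling. HOMER 4.11, Trim Galore 0.6.10, Bowtie2, Picard and deepTools 3.5.5 are named per the submitters' processing notes, as are the genome builds hg38 and mm10. Cells were fixed with formaldehyde for histone marks and with disuccinimidyl glutarate and formaldehyde for transcription factors, per the labels' protocols. Per the file headers, a peak had to exceed the input 4-fold at a Poisson p of 1e-04 and the surrounding 10 kb 4-fold, at a false discovery rate of 0.001, with tags scaled to 10 M. A list therefore depends on its input as well as on the precipitation: the filter against input removed 97.8% of putative peaks with dTAG13 and 80.2% with DMSO, and 80.9% with doxycycline and 47.4% without.

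The deposited columns give the position, an identifier and a constant 1 for each peak, per the file headers and values; no score is among the columns, and the peaks of a list have 1 width, except 1 DMSO peak. The comparisons planned by score or width were therefore made by the order of peaks in the file. Within chromosomes this order followed the numbers in the peak identifiers (lowest Spearman correlation 0.988), and it is taken here as the order of strength, which is an assumption. Ranks were used within a list only.

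Total tags per library, per the file headers, were 43.9 M (DMSO), 38.6 M (dTAG13), 34.1 M (FS2 in TetR cells), 36.3 M (FS2 in TetR-MybTA cells), 34.3 M (TetR), 44.0 M (TA2), 22.1 M (no doxycycline) and 22.5 M (doxycycline). Groups came from the titles and treatments, with 1 library in each. Shares were given with exact Clopper-Pearson intervals at 95%, which cover counting error over peaks and not the spread between cultures.

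Peaks were called shared when they overlapped by at least 1 bp. Overlap shares of whole lists, and of the 100 strongest FS2 sites with H3K27ac peaks, were set beside 100 circular shifts of the partner list within chromosomes. Other shares, such as those by rank group or within 1 kb, were not, except that the share of TetR FS2 sites near a gene end was set beside 1 shift. Shares expected from rank were means over peaks of the same list in 50 groups by rank, or 100 groups for chromosomes. Regions of SEM cells were compared in windows of 100 kb. Mouse genes were the 21631 protein-coding genes on autosomes and X of the GRCm38.p6 annotation, which is mm10. It gives no strand, so a gene was counted as having a peak when one lay within 1 kb of either end, in place of the planned transcription start, and peaks were counted within 50 kb of either end. Of 182 entries in the mouse gene lists, 181 were matched. The 160 entries of the human lists, promoters in SEM cells and MYB motifs were not analysed here, since neither a human annotation nor a genome sequence was used.

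Named genes and regions followed a rule set before the data were examined: members of the fixed gene lists; up to 10 places with the strongest peaks lacking a partner in each direction; up to 10 genes, or windows in SEM cells, with the largest loss and gain; and the 10 strongest shared FS2 sites, in the order of the TetR-MybTA list, and the 5 strongest of each list. Many of the strongest unpartnered peaks were shifted by less than 1 kb, so those with no partner within 1 kb are named as well, a choice made after the data were seen. Windows given for peaks kept against rank, and further sites, were also chosen after their values were seen. Some places that the rule names are not reported here. Gene lists were set beside 10000 random lists of the same size matched on peak rank.

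Alternatives planned before the data were examined were an overlap of 50% of the shorter peak, a reciprocal overlap of 50%, peaks within 1 kb, the stronger 50% of each list by rank, lists at the same length, peaks merged within 1 kb, autosomes and X only, and gene windows of 0.5 kb and 2.5 kb, or 10 kb and 100 kb. The 100 and 500 strongest FS2 sites, the strongest of 10 equal groups of a list and whole genes were added after seeing the data. The overlap code was tested on simulated partners of the no doxycycline list of 17313 peaks: it recovered 100.0% of simulated shared peaks, and the rank-matched ratio was 0.483 for peaks simulated at 0.5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.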

Results

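The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from human and mouse cells. SEM is a human pro-B acute lymphoblastic leukaemia cell line that carries the t(4;11) translocation. Acetylated lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, was profiled in SEM cells whose transcription factor MYB carried an FKBP12(F36V) tag, through which the small molecule dTAG13 sends a protein to degradation, after 24 h with 0.5 µM dTAG13. The DMSO library is its control by title, and its labels do not state whether those cells carried the tag. The mouse cells were E14 (TOT2N variant) embryonic stem cells with a stably integrated construct for TetR, a bacterial DNA-binding protein, or for TetR-MybTA, TetR joined to MybTA. Doxycycline releases TetR from its DNA operator. An antibody to TetR, FS2, was used in both mouse lines, and H3K27ac was profiled in 4 mouse libraries. These are called TetR, TA2 (a TetR-MybTA library whose input was named together with that of TetR), doxycycline (TetR-MybTA with 1 µg/ml doxycycline) and no doxycycline (its control by title). There was 1 library per group, so no difference has a replicate check, no p-value is given, and the exact 95% Clopper-Pearson intervals cover counting error only.

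The libraries held from 22.1 M tags (no doxycycline) to 44.0 M (TA2), per the file headers. The SEM lists held 24346 peaks with DMSO and 6000 with dTAG13. The mouse H3K27ac lists held 9141 (TetR), 8660 (TA2), 17313 (no doxycycline) and 7751 peaks (doxycycline). The FS2 lists held 31182 peaks with TetR and 1749 with TetR-MybTA. The approximate share of tags in peaks printed in the headers was 9.63% with DMSO, 5.87% with dTAG13, 8.93% for FS2 in TetR cells and 0.22% for FS2 in TetR-MybTA cells. The covered length was 6.94 Mb with DMSO, 1.62 Mb with dTAG13 and 0.546 Mb for FS2 in TetR-MybTA cells.

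**Figure D1:**
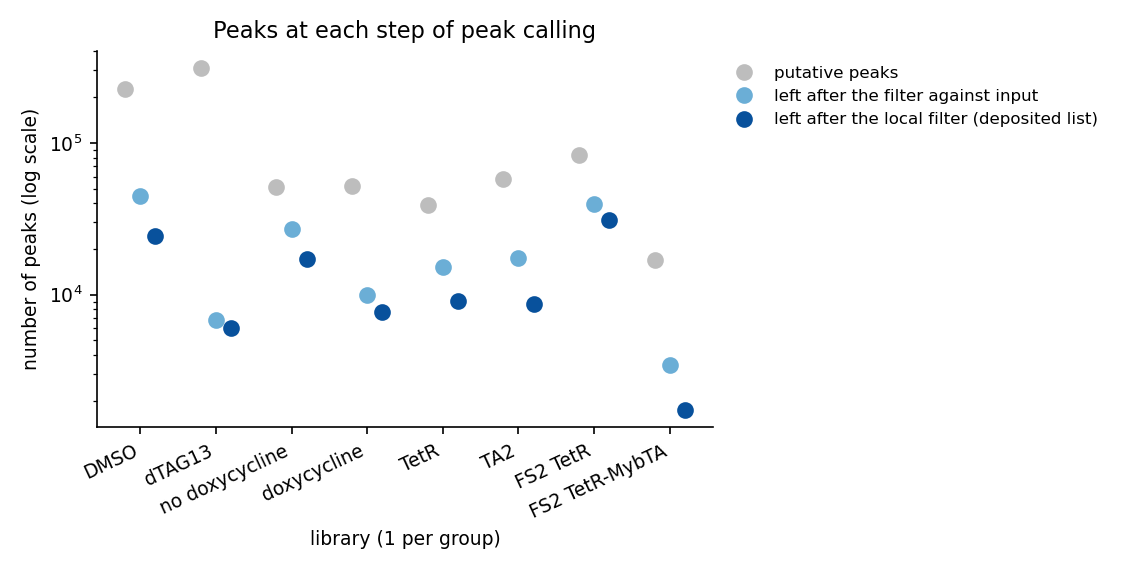
Number of peaks (vertical axis, log scale) at each step of peak calling for the 8 libraries (horizontal axis), as printed in the file headers; points are putative peaks, peaks left after the filter against input and the deposited list. dTAG13 had more putative peaks than DMSO (311859 against 226494) and fewer in its list (6000 against 24346).

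The SEM comparison asks which H3K27ac peaks were listed with DMSO and with dTAG13, the degrader of tagged MYB; the level of MYB was not measured here. With dTAG13 the H3K27ac list was 4.06 times shorter, and nearly all that remained lay at DMSO peaks. Of the 24346 DMSO peaks, 5547 overlapped a dTAG13 peak by at least 1 bp (22.8%, interval 22.3 to 23.3), and of the 6000 dTAG13 peaks 5547 overlapped a DMSO peak (92.5%, interval 91.8 to 93.1). After circular shifts of the partner list the mean shares were 0.141% and 0.585%. Peaks with a partner were the strong ones: with the DMSO list in 10 equal groups by rank, the share was 81.0% in the strongest group, 61.6% in the next, 46.4% in the third and 0.082% in the seventh. With the DMSO list shortened to 6000 peaks, 67.4% of each list overlapped the other.

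Fewer peaks were listed with dTAG13 in most regions of the SEM genome (hg38). In windows of 100 kb, 9442 of the 10527 windows with a peak held fewer dTAG13 than DMSO peaks, 1033 held as many and 52 held more. The largest losses were on chromosome 7 (92700001 to 92800000), from 20 peaks to 0, and on chromosome 9 (37200001 to 37300000), from 26 to 6. Adjacent windows of chromosome 5 (88700001 to 88800000 and 88800001 to 88900000) went from 14 to 0 and from 21 to 5. A window of chromosome 12 (25000001 to 25100000) went from 19 to 6, and one of chromosome 13 (40900001 to 41000000) from 12 to 0. Losses of this size went with low ranks: the ranks of the peaks alone would have kept 0.39 of the 20 peaks in the chromosome 7 window and 3.43 of the 26 in the chromosome 9 window, where 6 were kept. The largest gain was on chromosome 14 (101800001 to 101900000), from 8 to 12 peaks. Against their ranks, the fewest peaks were kept on chromosome 17 (81400001 to 81500000), 0 of 5 where 3.36 would have been kept by rank, and the most on chromosome 6 (26100001 to 26200000), 11 of 13 where 6.94 would have been.

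The strongest DMSO peaks with no overlapping dTAG13 peak were on chromosome 13 (27450268 to 27450552, rank 43), chromosome 2 (231615101 to 231615385, rank 60) and chromosome 8 (123396044 to 123396328, rank 98). A dTAG13 peak lay within 1 kb of the chromosome 2 peak but of neither other. A second peak on chromosome 13 (27424755 to 27425039, rank 131) also had none within 1 kb. In the reverse direction, the strongest dTAG13 peaks with no DMSO peak were on chromosome 4 (6938012 to 6938281, rank 65) and chromosome 17 (58332129 to 58332398, rank 97), and neither had a DMSO peak within 1 kb. No human annotation was used here, so peaks of SEM cells are given by position and no gene is named for them.

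**Figure D2:**
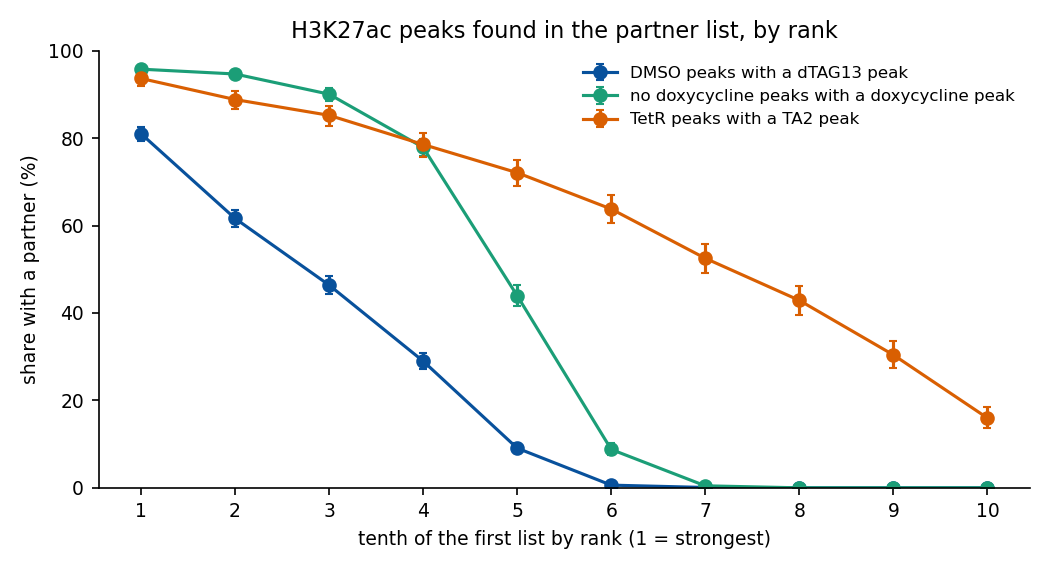
Share of peaks with an overlapping peak in the partner list (vertical axis, percent) in each of 10 equal groups of the first list by rank (horizontal axis, 1 is the strongest); points are shares of 1 pair of libraries and bars exact 95% intervals for counting error. The share of DMSO peaks with a dTAG13 peak went from 81.0% in the first group to 9.08% in the fifth, where that of TetR peaks with a TA2 peak was 72.1%. These shares depend on list length: the dTAG13 list holds 6000 peaks against 24346 with DMSO, and the TA2 list 8660 against 9141 with TetR. At the same list length they were 67.4% (DMSO in dTAG13) and 65.1% (TetR in TA2).

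The FS2 lists answer where in the mouse genome (mm10) the antibody to TetR gave peaks with each construct. Whether these sites hold the DNA operator of TetR was not examined, since no genome sequence was used. The strongest sites of TetR-MybTA lay next to Pvalb, the gene of the calcium-binding protein parvalbumin (chromosome 15, 78190929 to 78191240, 28 bp from a gene end), near AF366264 (chromosome 8, 13847872 to 13848183) and 44300 bp from Lamc1, a laminin chain gene (chromosome 1, 153376931 to 153377242). Next came sites inside Slc47a1 (chromosome 11, 61345833 to 61346144), Il9r, an interleukin receptor gene beside the alpha-globin genes (chromosome 11, 32196175 to 32196486), Duox1 (chromosome 2, 122335496 to 122335807) and Kalrn (chromosome 16, 33971141 to 33971452). Sites nearest to Rala (chromosome 13, 17843096 to 17843407), Tank (chromosome 2, 61663533 to 61663844) and Tspan32 (chromosome 7, 142991484 to 142991795) completed the 10 strongest, all of which were also in the TetR list. The 5 strongest TetR sites, nearest to Zfp640, Diablo, Arhgap29, P4ha1 and Helb, were absent from the TetR-MybTA list.

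Of the 1749 TetR-MybTA sites, 972 overlapped a TetR site (55.6%, interval 53.2 to 57.9), against a mean of 0.729% after shifts. They were 3.12% of the TetR list (interval 2.93 to 3.32). Among the 100 strongest sites of each list, 81 of TetR-MybTA were in the TetR list and 6 of TetR were in the TetR-MybTA list. TetR-MybTA sites lay within 1 kb of either end of a protein-coding gene in 3.09% of cases (interval 2.33 to 4.01), TetR sites in 10.2% (interval 9.88 to 10.6) and TetR sites after 1 circular shift in 2.97%. For the 1749 strongest TetR sites the share was 22.1% (interval 20.2 to 24.1). Since the lists differ 17.8 times in length, shared counts depend on it: with the TetR list shortened to 1749 sites, 112 were shared.

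H3K27ac at the FS2 sites addresses whether acetylated regions coincide with the peaks of the antibody to TetR. Among the 100 strongest TetR-MybTA sites, a number chosen after the data were seen, 51 overlapped an H3K27ac peak without doxycycline (interval 40.8% to 61.1%) and 28 did in TA2 (interval 19.5% to 37.9%). In the doxycycline list 4 did (interval 1.1% to 9.93%) and in the TetR list 6 (interval 2.23% to 12.6%). With all H3K27ac lists at the same length of 7751 peaks the counts were 40, 26, 4 and 6. With the stronger 50% of each H3K27ac list they were 41, 8, 4 and 5, so the gap between TA2 and TetR rested mostly on the weaker peaks of the TA2 list. The sites inside or nearest to Pvalb, Slc47a1, Il9r, Duox1, Kalrn, Tank and Tspan32 had an H3K27ac peak within 1 kb in both the no doxycycline and TA2 lists and in neither the doxycycline nor the TetR list. The site by Rala had one in the TetR list as well, that near AF366264 in the TA2 list alone, and that by Lamc1 in the TetR, no doxycycline and doxycycline lists.

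Over all 1749 TetR-MybTA sites, 27.9% overlapped a no doxycycline peak, 12.6% a TA2 peak, 10.1% a TetR peak and 8.75% a doxycycline peak, against shifted means of at most 0.376%. At the same list length these shares were 11.4%, 9.26%, 8.0% and 8.75%, and counting peaks within 1 kb they were 23.8%, 25.5%, 25.1% and 21.6%. Of the 100 strongest TetR sites, 40 overlapped a no doxycycline peak, 15 a TA2 peak, 21 a TetR peak and 20 a doxycycline peak with full lists. At the same list length these counts were 23, 15, 20 and 20, with overlapping intervals. Over all TetR sites the shares with full lists were 7.47% (no doxycycline), 3.21% (TA2), 3.36% (TetR) and 3.11% (doxycycline).

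**Figure D3:**
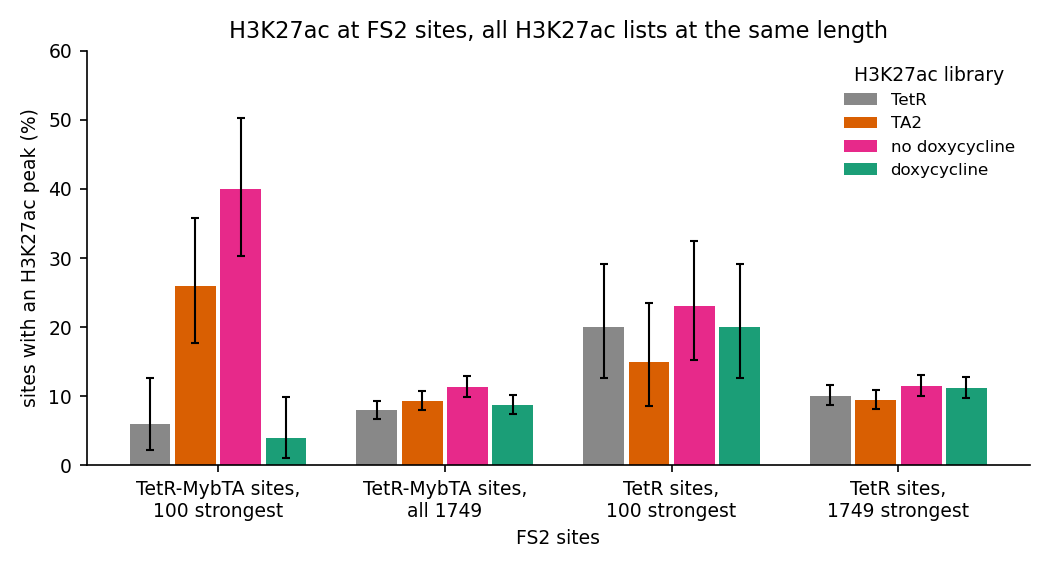
Share of FS2 sites that overlap an H3K27ac peak (vertical axis, percent) for 4 sets of sites (horizontal axis) and the 4 mouse H3K27ac libraries (colours), each H3K27ac list shortened to its 7751 strongest peaks; error bars are exact 95% intervals for counting error. Of the 100 strongest TetR-MybTA sites, 40 had a no doxycycline peak and 26 a TA2 peak, against 6 with a TetR peak and 4 with a doxycycline peak.

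**Figure D4:**
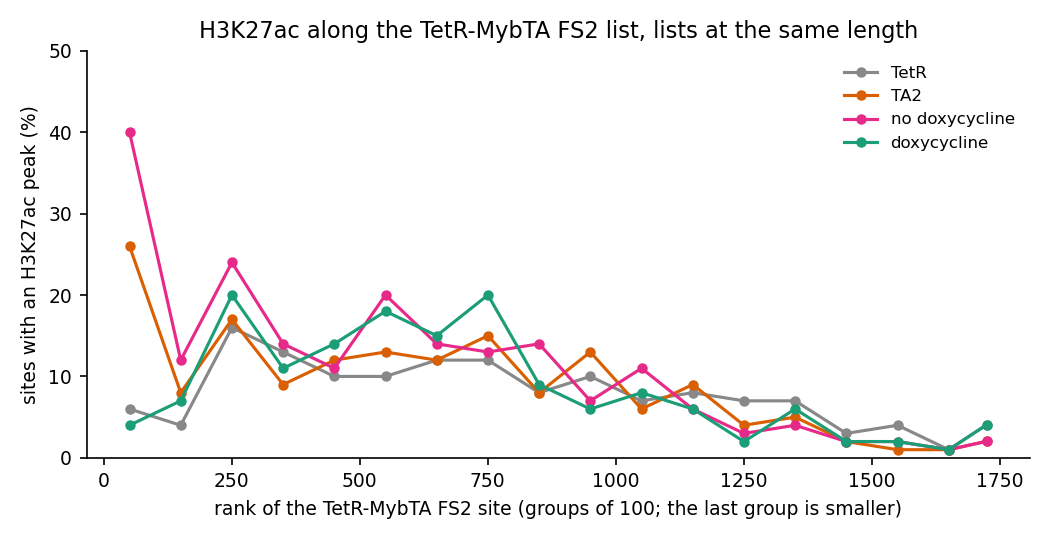
Share of TetR-MybTA FS2 sites that overlap an H3K27ac peak (vertical axis, percent) in groups of 100 sites by rank (horizontal axis), with each H3K27ac list shortened to 7751 peaks and 1 library per line. The libraries stand apart in the first group, with 40 of 100 sites without doxycycline and 4 of 100 with it, and the lines lie closer together and cross in later groups.

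The doxycycline comparison asks which H3K27ac peaks of TetR-MybTA cells were listed with and without doxycycline. Whether it released TetR-MybTA from the FS2 sites was not measured here. Without doxycycline, Kalrn, a guanine nucleotide exchange factor gene (chromosome 16, 33971356 to 33971641), held the strongest peak with no doxycycline peak within 1 kb, at rank 131. Next came peaks inside or nearest to Dennd5b (rank 164), Ppp1r10 (rank 181) and Pvalb (rank 284), and then Arrdc3, H2al1j, Rapgef4, Setd5, Tank and Il9r. The peaks nearest to Pvalb, H2al1j and Tank lay between genes, at 278, 46223 and 9369 bp from the gene. At 6 of these 10 places, those of Kalrn, Dennd5b, Pvalb, Rapgef4, Tank and Il9r, a TetR-MybTA FS2 site lay within 1 kb. Peaks inside or nearest to Ect2, Alkbh1, Eif5a, Hexim1, Hnrnpa3 and Psme4 (at 21761 bp from Psme4) had no overlapping doxycycline peak but had one within 1 kb. In the doxycycline list, peaks nearest to Nlrp12 (rank 269), Tuba1c (rank 508) and Smarcad1 (rank 570) were among the strongest with no partner within 1 kb. Of the 10 strongest such doxycycline peaks, 4 had a TetR-MybTA FS2 site within 1 kb: those nearest to Dusp27 and Fbxo15 and both nearest to Zfp236. Over the whole lists, 1184 of 17313 no doxycycline peaks and 478 of 7751 doxycycline peaks had such a site within 1 kb.

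In total 7127 of 17313 no doxycycline peaks overlapped a doxycycline peak (41.2%, interval 40.4 to 41.9), and 7127 of 7751 doxycycline peaks overlapped a no doxycycline peak (91.9%, interval 91.3 to 92.5). In 10 equal groups by rank, the share of no doxycycline peaks with a partner was 95.8% in the strongest, 44.0% in the fifth and 0.462% in the seventh. At the same list length it was 86.2% in both directions. Of the genes with the largest loss of covered length within 50 kb, Msi1, an RNA-binding protein gene, went from 14 peaks to 3, Plxna3 from 8 to 0, Sipa1l3 from 9 to 1 and Mgat5b from 10 to 2; the ranks of the peaks alone would have kept 3.91, 0.14, 1.47 and 4.96. The largest gains were of 2 peaks, as at Trim71 (from 5 to 7) and Scd4 (from 4 to 6).

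A peak lay within 1 kb of either end of 20 of the 24 cell cycle genes without doxycycline and 19 of these had one with it, among them Ccnb1, Cdk1 and Top2a, and the exception was Mki67. These 19 of 20 lay below the mean kept share of 98.2% for random lists matched on rank, and 65.2% of all genes with a peak kept one. For naive pluripotency genes the counts were 10 of 25 and 6: Klf4, Tbx3, Utf1, Gdf3, Dppa4 and Tet2 had a peak in both lists, Klf2, Klf5, Tfcp2l1 and Lin28a in the no doxycycline list alone, and Sall4 in the doxycycline list alone. Within 2.5 kb of a gene end Sall4 had a no doxycycline peak as well, at rank 2068. Housekeeping genes went from 12 of 20 to 11 in both, MYB-associated genes from 5 of 22 to 3 (Ccnb1, Mat2a and Hspa8, without Gata3 and Cebpb), and genes of the alpha-globin list from 5 of 12 to 3 (Nprl3, Mpg and Luc7l). Luc7l is counted in this list but lies on chromosome 17 in the mouse, while Nprl3 and Mpg lie at the locus on chromosome 11. The other members with a peak, Il9r and Snrnp25, shared the same no doxycycline peak between them, at rank 7518. Of formative and primed genes 2 of 13 had a peak without doxycycline (Zic2 and Zic5) and 0 with it. Lamb1 (endoderm), Bmp4 (mesoderm) and Gata3 (trophoblast) had a peak without doxycycline only, and no gene of the neural or two-cell-like lists had one in either list. Among 10000 random gene lists matched on rank, the kept shares lay at percentile 42.7 (naive pluripotency), 18.0 (cell cycle), 44.9 (housekeeping), 42.0 (MYB-associated) and 6.97 (alpha-globin locus), as a description of these libraries. Over all lists 55 of 176 genes had a peak without doxycycline and 41 of these with it (percentile 3.37). With the no doxycycline list shortened to 7751 peaks, 6 naive pluripotency genes, 3 MYB-associated genes and no formative and primed, endoderm, mesoderm or trophoblast gene had a peak in it. Promoters and 3′ ends were not told apart, because the annotation used gives no strand.

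The TetR and TA2 lists compare H3K27ac in cells with TetR and with TetR-MybTA. In TA2, peaks inside or nearest to Sulf2 (rank 531), Rapgef4 (rank 595), Rab12 (rank 627), Kalrn (rank 704), Pvalb (rank 732), Tns3, Enc1, Il9r, Sox2 and N4bp1 were the strongest with no TetR peak within 1 kb. Those of Rab12, Pvalb, Enc1 and N4bp1 lay between genes, at 15153, 292, 231837 and 181303 bp from the gene. Those of Rapgef4, Kalrn, Pvalb, Tns3 and Il9r had a TetR-MybTA FS2 site within 1 kb. The strongest TetR peaks with no TA2 peak within 1 kb were nearest to Med26 (rank 75), Phc1 (rank 116), Gpx4 (rank 141), Fbrsl1, Irak3, Pcmtd1, Cbfa2t2, Mllt6, Tmprss12 and Ranbp17, of which those of Pcmtd1 and Ranbp17 had such a site. Over the whole lists, 667 of 8660 TA2 peaks and 718 of 9141 TetR peaks had such a site within 1 kb. Within 50 kb, Impa2 went from 1 peak with TetR to 6 in TA2, and Ahcy, Pls3, AF366264 and Champ1 from 0 to 4, while Zfp469 went from 5 to 0 and Akap12 from 8 to 4, where ranks alone would have kept 2.7 and 6.39. AF366264 and Champ1 are close together on chromosome 8 and their windows overlap, so the same peaks can count for both.

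Of 9141 TetR peaks, 5704 overlapped a TA2 peak (62.4%, interval 61.4 to 63.4), and the same number of 8660 TA2 peaks overlapped a TetR peak (65.9%, interval 64.9 to 66.9). Cell cycle genes had a peak in 20 of 24 cases with TetR and 18 of these in TA2 (not Cdk2 and Plk1), naive pluripotency genes in 9 of 25 and 8, housekeeping genes in 10 of 20 and all 10, and MYB-associated genes in 4 of 22 and 3. Within 2.5 kb of a gene end Cdk2 had a TA2 peak as well, at rank 2854. Sox2, a pluripotency factor gene, had a peak in TA2 alone. Formative and primed genes had a peak in 3 of 13 cases with TetR (Zic2, Zic5 and Lefty1), of which Zic5 kept it, and Nodal had one in TA2 alone. Within 2.5 kb of a gene end Nodal had a TetR peak as well, at rank 1033. Genes of the alpha-globin list had a peak in 2 of 12 cases (Rhbdf1 and Luc7l), of which Luc7l kept it, and Nprl3 and Mpg had one in TA2 alone. Luc7l lies on chromosome 17, away from the locus on chromosome 11. No endoderm, mesoderm, neural or two-cell-like gene had a peak in either list, and Gata3 had one with TetR alone. The kept shares lay at percentile 42.9 (naive pluripotency), 0.7 (formative and primed, 3 genes), 22.0 (cell cycle), 62.4 (housekeeping) and 37.4 (MYB-associated) among random lists. Over all lists 47 of 176 genes had a peak with TetR and 40 of these in TA2 (percentile 3.03).

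The no doxycycline and TA2 libraries are both from TetR-MybTA cells without stated doxycycline, and the labels do not call them replicates. Their depth differed (22.1 M against 44.0 M tags), as did the share of tags in peaks printed in the headers (8.37% against 2.79%). Their overlap is therefore not a measure of the spread within 1 line. Of 8660 TA2 peaks, 6874 overlapped a no doxycycline peak (79.4%, interval 78.5 to 80.2), and these were 39.7% of the no doxycycline list (interval 39.0 to 40.4). Of TetR peaks 71.9% overlapped a no doxycycline peak (interval 71.0 to 72.8) and 51.8% a doxycycline peak (interval 50.8 to 52.9).

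Peaks shared by TA2 and no doxycycline and absent from TetR and doxycycline numbered 1016. The other ways of choosing a pair of lists gave 1643 (doxycycline and no doxycycline), 1020 (TetR and no doxycycline), 655 (TA2 and TetR), 76 (doxycycline and TetR) and 63 (doxycycline and TA2), each counted in the shorter list of the pair. At the same list length TA2 and no doxycycline shared 197 such peaks, fewer than doxycycline and no doxycycline (1467) or TA2 and TetR (1040), the pairs whose inputs were named together. Of the 197 peaks, 22.8% lay within 1 kb of a TetR-MybTA FS2 site (interval 17.2 to 29.3), against 7.23% (interval 5.95 to 8.67) and 9.62% (interval 7.89 to 11.6) in those pairs. The remaining pairs had 14.1% (doxycycline and TetR, interval 8.55 to 21.3), 11.3% (TetR and no doxycycline, interval 6.16 to 18.6) and 7.81% (doxycycline and TA2, interval 3.81 to 13.9), and the first and the next of these intervals overlap that of TA2 and no doxycycline. With full lists the share was 12.3% for TA2 and no doxycycline (interval 10.3 to 14.5), 15.8% for doxycycline and TetR (interval 8.43 to 26.0) and 10.8% for TetR and no doxycycline (interval 8.95 to 12.9). Of the 197 peaks 26 lay within 1 kb of the 100 strongest sites, against 0 (doxycycline and no doxycycline) and 2 (TA2 and TetR).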

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

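The strongest of 10 equal groups, the 100 and 500 strongest FS2 sites, the stronger 50% of the H3K27ac lists alone and whole genes were chosen after seeing the data; the other alternatives were planned. There are no replicates, so a share counts as moved when it left its interval for counting error, a peak number, covered length, count or ratio counts as moved only when it changed by more than 1.5 times, and the cause of a move was not tested except where a list was shortened. No paired analysis was possible because every group has 1 library. SEM promoters, human gene lists and motifs were not run. Among the main results under settings chosen beforehand, 138 values stayed within these limits, all peak numbers and covered lengths among them, and 95 moved. What depth limits was not tested; no doxycycline and doxycycline had 22.1 M and 22.5 M tags, and the weakest no doxycycline peaks still had no partner.

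For shares of peaks with a partner, the list in parentheses is the one searched in the other. With an overlap of 50% of the shorter peak they were 90.8% (dTAG13 in DMSO), 60.4% (TetR in TA2), 63.8% (TA2 in TetR), 40.2% (no doxycycline in doxycycline), 89.7% (doxycycline in no doxycycline) and 74.5% (TA2 in no doxycycline). With a reciprocal overlap of 50% they were 90.6% (dTAG13 in DMSO), 60.4% (TetR in TA2), 63.8% (TA2 in TetR), 40.2% (no doxycycline in doxycycline), 89.7% (doxycycline in no doxycycline) and 74.5% (TA2 in no doxycycline). With peaks within 1 kb matched they were 26.0% (DMSO in dTAG13), 98.2% (dTAG13 in DMSO), 69.2% (TetR in TA2), 72.3% (TA2 in TetR), 44.9% (no doxycycline in doxycycline), 97.6% (doxycycline in no doxycycline) and 90.5% (TA2 in no doxycycline). In the stronger 50% of each list they were 23.4% (DMSO in dTAG13), 94.8% (dTAG13 in DMSO), 72.8% (TetR in TA2), 76.9% (TA2 in TetR), 42.4% (no doxycycline in doxycycline), 94.8% (doxycycline in no doxycycline) and 86.6% (TA2 in no doxycycline). At the same list length they were 67.4% (DMSO in dTAG13), 67.4% (dTAG13 in DMSO), 65.1% (TetR in TA2), 86.2% (no doxycycline in doxycycline), 86.2% (doxycycline in no doxycycline) and 63.6% (TA2 in no doxycycline). With peaks within 1 kb merged they were 94.9% (dTAG13 in DMSO), 64.6% (TetR in TA2), 67.3% (TA2 in TetR), 42.3% (no doxycycline in doxycycline), 94.3% (doxycycline in no doxycycline) and 81.3% (TA2 in no doxycycline). In the strongest of 10 groups they were 81.0% (DMSO in dTAG13) and 95.8% (no doxycycline in doxycycline). FS2 sites in both lists numbered 413 in the stronger 50% of the lists and 112 at the same length, and peaks of TA2 and no doxycycline alone 423 and 197.

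Shares of FS2 sites with an H3K27ac peak are given in the order TetR, TA2, no doxycycline, doxycycline. With an overlap of 50% of the shorter peak they were 3.15%, 4.63%, 10.7% and 3.03% at TetR-MybTA sites, then 1.52%, 1.51%, 3.55% and 1.60% at TetR sites. With a reciprocal overlap of 50% they were 2.80%, 4.23%, 9.55% and 2.69% at TetR-MybTA sites, then 1.51%, 1.501%, 3.53% and 1.60% at TetR sites. With peaks within 1 kb matched they were 32.0%, 32.5%, 52.8% and 21.6% at TetR-MybTA sites, then 12.5%, 11.2%, 20.1% and 9.61% at TetR sites. In the stronger 50% of each list they were 5.49%, 3.78%, 20.6% and 5.26% at TetR-MybTA sites, then 2.66%, 2.39%, 6.16% and 2.91% at TetR sites. At the same list length they were 8.01%, 9.26%, 11.4% and 8.75% at TetR-MybTA sites, then 2.75%, 2.74%, 3.19% and 3.11% at TetR sites. With peaks within 1 kb merged they were 14.5%, 15.3%, 34.0% and 11.3% at TetR-MybTA sites, then 4.29%, 3.82%, 8.87% and 3.64% at TetR sites. For the 100 strongest TetR-MybTA sites they were 6%, 28%, 51% and 4%. For the 500 strongest they were 10%, 15.8%, 31.8% and 11.2%. For the 100 strongest at the same list length they were 6%, 26%, 40% and 4%. For the 100 strongest with the stronger 50% of each H3K27ac list they were 5%, 8%, 41% and 4%. For all sites with the stronger 50% of each H3K27ac list they were 3.32%, 2.00%, 12.9% and 3.09%. The difference between TA2 and TetR changed sign to -1.72 percentage points for the 874 strongest TetR-MybTA sites, when these and the H3K27ac lists were each cut to the stronger 50%, and to -1.32 percentage points for all sites when the H3K27ac lists alone were cut.

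Counts of list genes with a peak in both TetR and TA2 moved for naive pluripotency to 5 within 0.5 kb of a gene end, for formative and primed genes to 3 within 2.5 kb, 0 within 0.5 kb and 2 over whole genes, and for neural genes to 1 within 2.5 kb. Between no doxycycline and doxycycline, formative and primed, endoderm and neural genes moved from 0 to 1 within 2.5 kb, and formative and primed, endoderm and trophoblast genes from 0 to 1 over whole genes.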

Other observations

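The tests of neighbouring peaks and of chromosome 8 by peak order were written before their results were seen; all other tests in this part, and the controls of the neighbour test, were chosen after. Around the genes of the alpha-globin list, peaks within 50 kb of a gene end numbered 6 with TetR, 21 in TA2, 28 without doxycycline and 17 with doxycycline, where peaks near several genes count once for each gene. Of these, 1, 1, 2 and 2 were at Luc7l, which lies on chromosome 17 and not at the locus on chromosome 11. At Nprl3, a gene whose introns hold alpha-globin enhancers, these counts were 1, 3, 4 and 2. Around formative and primed genes they were 31, 26, 38 and 14, and around endoderm genes 6, 9, 18 and 9.

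The SEM list with dTAG13 was 4.06 times shorter than with DMSO. Fewer tags did not lower the number of putative peaks: its ratio, dTAG13 to DMSO, was 1.38, and that of total tags was 0.878. However, putative peaks were called at a lower tag threshold with dTAG13 (17 against 20), and the depth of the inputs was not examined. The test therefore does not exclude an effect of depth at the later filters. The drop appeared at the filter against input, after which the ratio was 0.153; this says where peaks left the list, and a weaker precipitation, a different input and less H3K27ac may each act there. Neighbouring strong DMSO peaks shared their fate in 89.1% of 440 pairs, above the highest of 100 shuffles (82.0%), which the test as written took as evidence against 1 common threshold. That criterion was unsound. Peaks with a neighbour were kept more often (92.8% against 83.4%), and 1 dTAG13 peak within 1 kb can count for both of a pair. Shuffled among peaks with a neighbour the highest value was also 89.1%, and by overlap the share was 73.2% (shuffles 66.6 to 76.6%). Both peaks were lost in 5 pairs, so this test cannot tell locus-specific loss from a common threshold. The kept share on chromosome 8, given below, was a separate comparison.

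An H3K27ac peak lay at 51 of the 100 strongest TetR-MybTA FS2 sites without doxycycline and at 4 with it. The length of the lists does not account for it, since the difference was 36.0 percentage points at the same length. Nor does a filter that was stricter alike for all peaks of the same rank. The 80 no doxycycline peaks within 1 kb of these sites were kept 57.2 percentage points less often than peaks of the same rank elsewhere. For this and the next kept shares, peaks at the sites lay within 1 kb of one. Kept here means a partner peak within 1 kb, not an overlap. The filter against input acts place by place and the inputs were not used, so a stricter filter at these sites was not excluded. TA2 peaks at these sites were kept in the TetR list in 30.9% against 78.5% for the same rank. Over all 1749 sites no doxycycline peaks were kept in 41.0% against 43.9%, and TA2 peaks in the TetR list in 70.9% against 59.1%. Over all sites the gap of no doxycycline peaks was thus 2.9 percentage points (interval of the kept share 38.1 to 43.8). That of TA2 peaks in the TetR list was reversed. A lasting difference between the lines, such as copy number, would not by itself separate the doxycycline library from the no doxycycline library. Both are labelled TetR-MybTA. That the doxycycline list had a peak at 4.0% of these sites is part of the pattern itself, so it is not a separate test. TetR-MybTA bound at the site is a candidate explanation: TA2 exceeded TetR by 20 percentage points at these sites at the same length, but by 3 with the stronger 50% of each H3K27ac list, where TA2 fell below TetR over all 1749 sites (a difference of -1.32 percentage points). The series holds no FS2 library labelled with doxycycline and each condition is 1 library, so this stays a hypothesis.

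The FS2 list of TetR was 17.8 times longer than that of TetR-MybTA, and its strongest sites were others. Sequencing depth does not account for this (ratio of total tags, TetR-MybTA to TetR, 1.06), nor does the filter against input alone (ratio of putative peaks before it 0.206). A weaker precipitation that kept the order of the sites would leave the strongest TetR sites listed, and 6.40% of the strongest 1749 were in the TetR-MybTA list. This restates that the strongest sites differed and is not a separate test. In the other direction, 972 of the 1749 TetR-MybTA sites, and 81 of the 100 strongest, were in the TetR list. The share of tags in peaks was 0.22% with TetR-MybTA and 8.93% with TetR, so a weaker precipitation as a part of the cause is not excluded. A higher level of TetR protein, or another background of the antibody, may contribute and was not tested.

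On chromosome 8 (hg38), SEM peaks were kept less often than peaks of the same rank elsewhere: 190 were kept and 260.2 expected, a ratio of 0.73, while the other chromosomes lay between 0.901 and 1.13. The hypothesis that 1 locus or arm carries the difference was tested on both parts of the chromosome split by peak order. The ratios were 0.747 (232416 to 73293504) and 0.715 (73293948 to 145052844), but both parts can hold some of the long arm. Split at the longest stretch without a DMSO peak (43233496 to 46263072), which spans the centromere, the ratios were 0.724 (exact Poisson interval 0.555 to 0.928) and 0.733 (interval 0.612 to 0.872), which argues against a deficit on 1 arm alone. In 10 groups of peaks by position the ratios ran from 0.557 (interval 0.288 to 0.973) to 0.982 (interval 0.623 to 1.474). The intervals of these groups are wide, so whether the deficit is even along the chromosome is not settled. No other explanation was tested.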
